A study of Mus musculus with 4 samples.

How the data were processed

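The series holds 4 arrays of OG2 mouse ES cells. Per the labels' protocols, no feeder cells were used and the ES cells grew on a gelatin coat in KSR medium with 1 µM PD0325901, 3 µM CHIR99021 and 1000 U/ml LIF, switched for 12 h to the media named in the report, and harvested directly on the dish. The doses of PD0325901 and LIF after the switch, the cell number and any repeat of the cultures are not given in the sources used here. Per the labels' protocols, total RNA was purified on columns with on-column DNA digestion, and 400 ng were amplified and labelled with Cy-3 over 12 h of in vitro transcription. Per the submitters' processing notes, BeadStudio was used; its version, the background subtraction and the normalization are not given in the sources used here.

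Per the file headers, each array's deposited table held for each probe a signal in units of intensity, the bead standard error of that signal, also an intensity, and a detection p-value. The deposited signals were read as mean bead intensities without background subtraction or normalization, since their lowest values lay between 64.4 and 71.2 and their medians differed between arrays. The deposited detection p-values moved in steps of 1/798, so 798 negative controls were taken to lie behind them; the controls themselves were not analysed here. The authors' value table held whole-number intensities for 13029 to 13040 of 25697 probes per array. Its values followed the signals (Spearman correlation across probes above 0.999) and had equal medians on the 4 arrays, so it was taken as background-subtracted and normalized; how this was done is not given in the sources used here.

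Signals were background-corrected with the limma function nec, using the detection p-values to estimate the background and an offset of 16, put on the log2 scale and quantile-normalized over all 4 arrays. Probes were taken to genes by the probe annotation of the series and the RefSeq gene table (GRCm38.p6). The build used by the authors is not given in the sources used here, so symbols and probe IDs are given and no coordinates. Of 25697 probes, 23978 had 1 symbol, 0 had several and 1719 had none. Probes with a detection p below 0.01 on at least 1 array (12089) were kept, and the probe with the highest mean normalized signal stood for its gene. This gave 8341 of 16593 genes, 2175 of them with more than 1 detected probe. A further 711 detected probes had no symbol; they were normalized with the rest and counted apart. Where a gene was detected on only 1 array of a difference, the fold was bounded as at least the fold between the detected signal and the other array's detection limit, or the other array's value where that was higher. Mean log2 differences and departures used the normalized values whether or not a probe was detected, and for genes not detected on an array they are printed with that stated and are uncertain in size.

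The 4 differences taken were FGF2 minus PD0325901 in each background and JAK inhibitor minus LIF in each background, with their means over the backgrounds and the departure from additivity. With 1 array per condition these differences have no test, and genes were counted at 2-fold. A limma fit with both factors as additive terms (lmFit and eBayes, Benjamini-Hochberg adjustment over 8341 genes) used the departure from additivity as its only error, with 1 residual degree of freedom. Its prior had 7.01 degrees of freedom and a standard deviation of 0.164. The p-values therefore assume that the factors add, and they measure the spread between these arrays only.

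The 22 gene lists were naive pluripotency, general pluripotency, ERK feedback and immediate early, LIF-JAK-STAT3 targets, formative and primed epiblast, primitive streak and mesendoderm, primitive endoderm, trophectoderm, neuroectoderm, Wnt and beta-catenin targets, Nodal and TGF-beta targets, BMP targets, interferon and MHC class I, glycolysis and hypoxia, cholesterol synthesis, cell cycle, p53 targets, amino acid and unfolded protein stress, heat shock, 2-cell-like and germ cell, fibroblast and feeder cells, and reference genes. For each, the median log2 difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Members past the test were counted with adjustment over all genes and adjusted over the list alone.

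The comparisons, thresholds, lists, alternatives and the rule for named genes were fixed before the data were examined. Named genes were, for each factor, the 10 largest positive and 10 largest negative means among genes at least 1.5-fold the same way in both backgrounds; list members at least 2-fold the same way in both; a set named in advance; and, for the departure, the 5 largest in each direction and list members of at least 2-fold. This gave 72 genes, of which 66 were analysed. List members that passed when adjusted over the list alone, and some further list members printed for context, were named after the values had been seen, as were the other called genes of the closing section. Of the named genes, 11 had 16 other detected probes.

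The alternatives were no background correction, normexp without control information (offset 50), scaling to the median of detected probes, no normalization between arrays, the authors' value table, no detection filter, detection on all 4 arrays, detection p below 0.05, the mean of a gene's probes, size thresholds of 1.5-fold and 4-fold, eBayes with an intensity trend or a robust prior, adjusted p thresholds of 0.01 and 0.1, and leaving out each array in turn.

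The steps were tried on simulated changes, additive by construction, put into 100 genes of each size, 200 for each factor. This gave more calls than the 20 and 24 in the data and so a looser cutoff on the unadjusted p. The shares recovered by the additive fit therefore overstate those for the data. There, S100a1 for FGF2 (mean log2 difference −1.05, adjusted p = 0.0555) and Chac1 for the JAK inhibitor (1.02, 0.0527) did not pass that fit. The additive fit recovered 86% of simulated 2-fold FGF2 changes and 84% of JAK inhibitor changes, and all of 4-fold, with 17 and 19 false calls beside 186 and 184 true ones over 8341 genes (8.37% and 9.36% of calls); the rule of 2-fold in both backgrounds recovered 26% and 22% at 2-fold. The background step returned a median of 0.94 of a simulated log2 change of 1 for probes more than 100 above background, 0.85 from 30 to 100, 0.63 from 10 to 30 and 0.10 under 10. Tools were R 4.3.3 with limma 3.58.1 and jsonlite 2.0.0, and Python 3.11.15 with matplotlib 3.10.9.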

Results

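Gene expression was measured in OG2 mouse embryonic stem (ES) cells, a line that carries a green fluorescent protein transgene under the control of Pou5f1 (Oct4), after 12 h of a change in signalling. The cells had been grown without feeder cells on gelatin in KSR medium with 1 µM PD0325901, an inhibitor of the kinase MEK that blocks activation of ERK, 3 µM CHIR99021, an inhibitor of the kinase GSK3, and 1000 U/ml of leukaemia inhibitory factor (LIF), a cytokine that activates STAT3 through JAK kinases. They were then switched to 4 media that crossed 2 factors: PD0325901 with LIF, fibroblast growth factor 2 (FGF2, 10 ng/ml) with LIF, PD0325901 with JAK inhibitor I (1 µM), and FGF2 with JAK inhibitor I. The labels name no CHIR99021 in any of the 4 media. Each condition was measured on 1 Illumina bead array, so no value below has a replicate of its condition. Of 25697 probes, 10677 were detected with PD0325901 and LIF, 10749 with FGF2 and LIF, 10626 with PD0325901 and the JAK inhibitor, and 10927 with FGF2 and the JAK inhibitor. The median bead standard error of probes detected on every array lay between 4.08% and 4.56% of the signal. The number of arrays limits the precision of every comparison, and bead errors cover the beads of 1 array only.

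The first comparison asked what changes when the ERK pathway is stimulated in place of being blocked: FGF2 against PD0325901, made once with LIF and once with the JAK inhibitor. In the labels FGF2 takes the place of PD0325901, so adding FGF2 and withdrawing the MEK inhibitor cannot be told apart. A change with FGF2 below covers both. Several ERK target and feedback genes rose with FGF2, while others such as Fos (0.09) and Dusp14 (−0.07) stayed close to 0. Egr1 (probe ILMN_2662926), an immediate early transcription factor, rose by a mean log2 difference of 3.77 ± 0.21 (SE, additive limma fit, adjusted p = 0.000787), being 10.3-fold higher with LIF and at least 14.8-fold higher with the JAK inhibitor, where it was not detected with PD0325901. The ERK phosphatases Dusp4 (ILMN_2689731) and Dusp6 (ILMN_2925711) rose 3.34-fold and 2.83-fold on average. Other probes gave log2 values of 1.02 (detected on 2 arrays) and 1.24 for Dusp4, and 1.31 and 1.55 (detected on 3 arrays) for Dusp6. The ETS factor Etv4 (ILMN_2778111) rose by a log2 value of 1.46 ± 0.15. The secreted factor Bmp4 (ILMN_1215252) rose by 1.70 ± 0.16 and Id1 (ILMN_2672190), a target of BMP signalling, by 1.98 ± 0.21. Lefty1 (ILMN_1246073), an extracellular antagonist of Nodal, was 2.96-fold lower on average (log2 −1.57 ± 0.18).

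Over 8341 genes, 103 differed at least 2-fold between FGF2 and PD0325901 with LIF (57 higher and 46 lower with FGF2), and 33 did so with the JAK inhibitor (23 higher, 10 lower). In both backgrounds, 20 genes differed at least 2-fold the same way, 17 higher and 3 lower, and 0 genes differed at least 2-fold in opposite directions, which is the count that the crossed split of the 4 arrays gives. In the additive limma fit, 20 genes passed an adjusted p of 0.05, again 17 higher and 3 lower (963 at unadjusted p below 0.05, where 417 would be expected by chance). The split of the calls varied with the processing, with 236 higher and 164 lower without background correction, 196 and 139 with normexp and an offset of 50, and 216 and 144 with an intensity trend in eBayes. Besides those above, the genes with the largest rises were Ccdc3 (1.85), the matrix metalloproteinase Mmp9 (1.63), the Snail family gene Snai3 (1.57), Inhba (1.55), which encodes a subunit of activin and was at least 3.00-fold higher with the JAK inhibitor, not being detected with PD0325901 there, the homeobox gene Gbx2 (1.54) and the receptor Robo4 (1.54), as mean log2 differences. The POU factor Pou3f1, which is expressed in the epiblast after implantation, rose by 1.42. The 3 genes that fell were Ccn5 (−1.64), which was at least 2.88-fold lower with LIF and at least 2.37-fold lower with the JAK inhibitor since it was not detected with FGF2, Lefty1, and the water and glycerol channel Aqp3 (−1.42). Among genes at least 1.5-fold the same way in both backgrounds, the next largest negative values did not pass the test: Lum (−1.32), AA467197 (−1.12), Crxos (−1.11), Dppa3 (−1.10), Spic (−1.05), S100a13 (−1.05) and S100a1 (−1.05). Of these, Lum and Spic were not detected with FGF2 in either background, where they were at least 3.19-fold and 1.68-fold lower with LIF and at least 1.47-fold and 1.18-fold lower with the JAK inhibitor.

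The 20 calls rest on the assumption that the factors add, with 1 residual degree of freedom per gene. In simulated data with 200 changed genes per factor, 8.37% of calls were false (9.36% for the JAK inhibitor). The simulated factors added by construction, so these shares do not cover factors that do not add. They are not the false share of the 20 calls. The number of calls depended strongly on the processing. In limma 0 genes passed with the authors' value table (768 at unadjusted p below 0.05) and 0 without a detection filter (1588). Without normalization between arrays 444 passed. For both factors the counts mostly rose with the degrees of freedom of the eBayes prior, which were 7.01 here. The prior had 2.67 with the authors' value table and 4.11 without a detection filter. It had infinite ones without normalization, without background correction, with normexp, with median scaling and with an intensity trend. Log2 differences of the 2 backgrounds correlated across genes with r = 0.33 over all genes and r = 0.46 among the brighter genes, and genes are not independent replicates.

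By gene list, 4 of the 18 analysed members of the ERK feedback and immediate early list rose over all genes tested and 10 adjusted over the list alone, with none falling. The list's median of 0.57 lay above all 10000 random lists matched on mean expression. Of its other members, Spry4 stood at 1.38, Phlda1 at 1.13, Junb at 0.91 and Spred1 at 0.83, none past the test over all genes. BMP targets had a median of 0.47 (percentile 99.93; 0.22 without background correction and 1.08 with detection on all 4 arrays), with Id1 and Bmp4 called of 5 members and also adjusted over the list alone, while Id3 stood at 0.21. Formative and primed epiblast genes had a median of 0.36, above all random lists. Of the 10, Pou3f1 rose, and 3 rose adjusted over the list alone, the others being Sox4 (0.65), detected only with FGF2 and the JAK inhibitor, and the DNA methyltransferase Dnmt3b (0.62; 0.30 on its other detected probe). Otx2 stood at 0.36, with −0.20 beside LIF and 0.91 beside the JAK inhibitor.

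General pluripotency genes had a median of 0.25 (percentile 99.95) with 0 of 10 past the test over all genes and 1 higher adjusted over the list alone, Lin28a at 0.77. Pou5f1 (0.03) and Sox2 (0.07) were close to 0, and a further detected probe of Sox2 gave −0.34. Naive pluripotency genes had a median of −0.08 (percentile 10.2). By background it was −0.11 (percentile 8.92) with LIF and −0.24 with the JAK inhibitor, there below all random lists. In both backgrounds 9 members were lower and 4 higher. Of the 15, Gbx2 rose; adjusted over the list alone, Gbx2 and Klf5 were higher and Nanog, Klf2, Klf4 and Dppa3 lower. Nanog stood at −0.59, Klf2 at −0.72, Esrrb at −0.02 and Tbx3 at −0.03. Klf4 stood at −0.60, while its other detected probes gave −0.08 and 0.38. Nodal and TGF-beta targets had a median of −0.07 (percentile 27.4), with Lefty1 called of 5 members and also adjusted over the list alone.

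Primitive endoderm genes had a median of 0.27 (percentile 99.8), and trophectoderm genes one of 0.26 (percentile 99.6), each with 0 of 10 past the test over all genes. The primitive endoderm median was 0.45 (99.94) with LIF but 0.13 (89.9) with the JAK inhibitor. It was 0.17 without background correction and 0.18 (95.2) with detection on all 4 arrays. The trophectoderm median was 0.22 (95.53) with LIF and 0.16 (94.05) with the JAK inhibitor. It was 0.10 without background correction and stood at percentile 97.03 with the authors' value table. Adjusted over the list alone, 3 primitive endoderm genes were higher and 1 lower, with Gata6 at 0.75 and Dab2 at −0.53, and 2 trophectoderm genes were lower, Gata2 at −0.60, not detected with FGF2 and the JAK inhibitor, and Tfap2c at −0.61. Primitive streak and mesendoderm genes had a median of 0.28 (percentile 95.9), being 0.35 (93.5) with LIF and 0.13 (70.7) with the JAK inhibitor. None of the 4 members was detected on every array. Of them 0 passed the test, and Gsc (−0.85), detected only with PD0325901 and LIF, was lower adjusted over the list alone. Wnt and beta-catenin targets had a median of 0.19 (percentile 89.3), with 0 of 5 past the test and Axin2 (0.75) higher adjusted over the list alone. Neuroectoderm genes had a median of 0.12 (percentile 71.5), with 0 of 3 past either adjustment. Genes of the interferon response and MHC class I had a median of −0.18 (percentile 2.02), with 0 of 8 past the test and B2m (−0.59) lower adjusted over the list alone.

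LIF-JAK-STAT3 targets had a median of 0.08 (percentile 87.8) for FGF2 against PD0325901, with Gbx2 called of 15, and 3 higher and 2 lower adjusted over the list alone. Glycolysis and hypoxia genes had a median of −0.01 (percentile 46.5), with 0 of 14 past the test and Pdk1 (0.79) higher adjusted over the list alone. No member passed either adjustment among cell cycle genes (median 0.08, percentile 87.4), cholesterol synthesis genes (0.05, 76.9), heat shock genes (0.02, 64.4), p53 targets (−0.01, 45.2), amino acid and unfolded protein stress genes (−0.03, 32.9), genes of the 2-cell-like state and germ cells (−0.05, 33.3) and reference genes (−0.02, 45.8). Fibroblast and feeder cell markers, fixed as a check for other cells, had a median of −0.36 (−0.15 without background correction), below all random lists, with 0 of 8 past the test and 2 lower adjusted over the list alone, Lum and Acta2. That list stood at −0.51 with LIF and at −0.08 with the JAK inhibitor, and Dcn and Lum were highest on the array of PD0325901 with LIF.

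**Figure D1:**
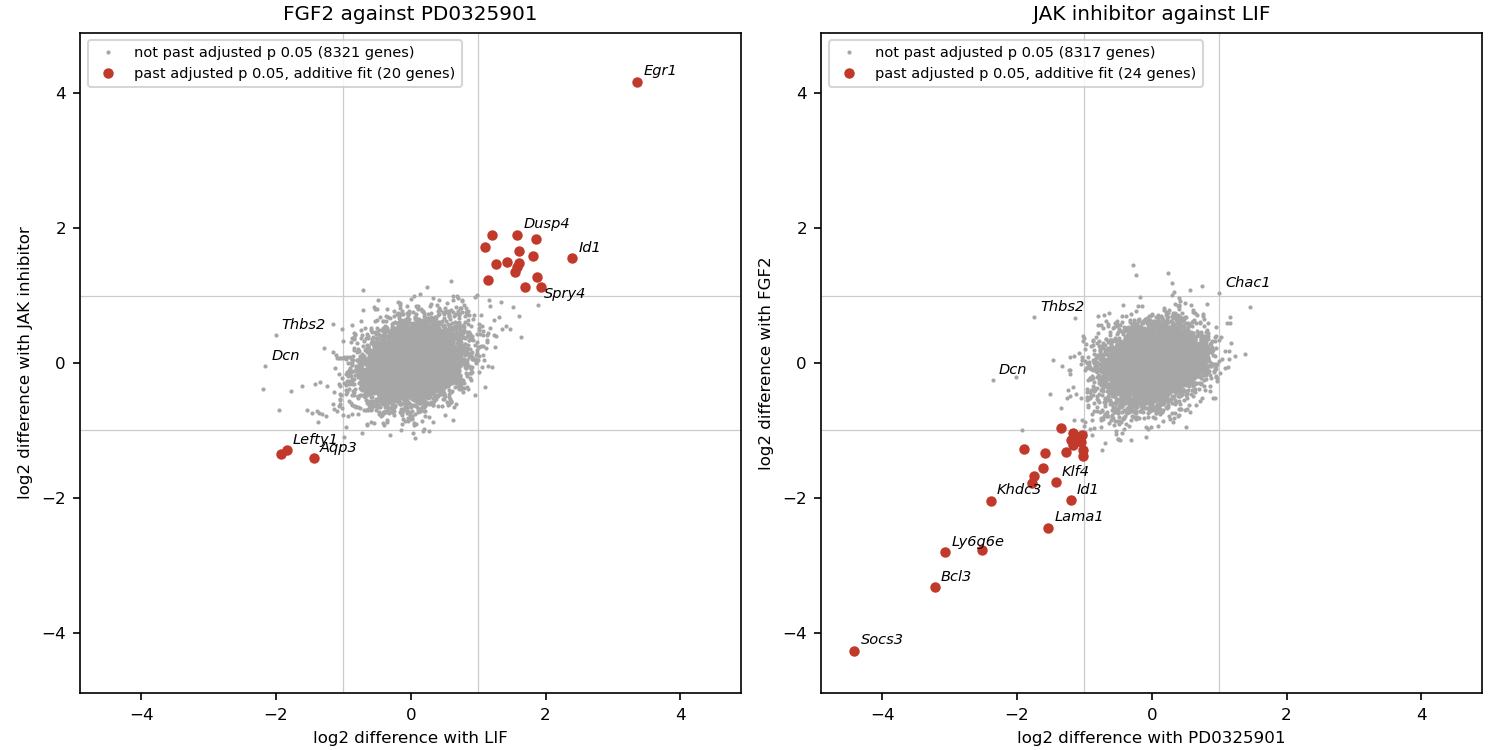
Log2 difference of each of 8341 genes in 1 background (horizontal) against the other (vertical), left for FGF2 against PD0325901 and right for the JAK inhibitor against LIF; each point is a gene, grey lines mark 2-fold, and red points passed the additive limma fit. The 20 red genes at left lie up to Egr1 at 3.36 and 4.17, the 24 red genes at right lie down to Socs3 at −4.41 and −4.27, and Dcn and Thbs2 lie apart, being highest on the array of PD0325901 with LIF.

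The second comparison asked what changes when JAK signalling is inhibited in place of being stimulated. The labels replace LIF by the JAK inhibitor, so the comparison covers both changes at once, and it was made once with PD0325901 and once with FGF2. Several genes of the LIF and STAT3 response fell with the inhibitor, while others such as Cebpb (0.11) did not. Socs3 (ILMN_2618176), the feedback inhibitor of JAK signalling, was 20.2-fold lower on average (log2 −4.34 ± 0.16, SE of the additive limma fit, adjusted p = 2.43e-05). Bcl3 (ILMN_2749717), a nuclear member of the I kappa B family, was not detected with the inhibitor and was at least 8.48-fold lower with PD0325901 and at least 8.06-fold lower with FGF2. Stat3 itself (ILMN_2698046) was 3.27-fold lower (−1.71 ± 0.15), Klf4 (ILMN_2999439), a naive pluripotency factor, 3.02-fold lower (−1.60 ± 0.16) and the AP-1 gene Junb (ILMN_1220034) 3.00-fold lower (−1.59 ± 0.19). Further detected probes of Stat3 gave −1.47 and −0.99, and those of Klf4 −1.82 and −1.71.

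With PD0325901, 69 genes differed at least 2-fold between the JAK inhibitor and LIF (15 higher and 54 lower with the inhibitor), and with FGF2 45 did (9 higher, 36 lower). Fewer genes being higher depended on the processing. Without normalization between arrays 24 were higher and 22 lower with FGF2, where the median of all genes also shifted from 0.01 to 0.20. At 1.5-fold 407 were higher and 379 lower with PD0325901. In both backgrounds 23 genes were at least 2-fold lower, 0 were at least 2-fold higher, and 0 differed at least 2-fold in opposite directions. The additive limma fit called 24 genes, all lower (884 of either direction at unadjusted p below 0.05, where 417 would be expected by chance). Among them, Ly6g6e was not detected with the inhibitor and was at least 6.69-fold lower with PD0325901 and at least 5.38-fold lower with FGF2. The serine protease inhibitor gene Spink1 fell, with a mean log2 difference of −2.65 (at least 6.62-fold lower with FGF2, where it was not detected with the inhibitor), as did Khdc3 (−2.22), the laminin chain gene Lama1 (−1.99), Urah (−1.78) and Id1 (−1.62). Tdgf1, which encodes the Nodal co-receptor Cripto, stood at −1.19 and Aqp3 at −1.13. Id1 and Aqp3 were the 2 genes called for both factors, where independent lists would share 0.058. The lists are not independent, since each gene had the same standard error in both tests, so that number does not measure an excess. Aqp3 was lower for both, and Id1 was higher with FGF2 and lower with the inhibitor.

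No gene was called higher with the JAK inhibitor. Among genes at least 1.5-fold the same way in both backgrounds, the largest positive values were those of the glycine transporter gene Slc6a9 (1.14), Chac1 (1.02, adjusted p = 0.0527), whose product degrades glutathione, Dgke (0.94), Fam171b (0.92), Pou3f1 (0.87), Tspan2 (0.85), Gm15107 (0.85), Psat1 (0.74) of serine synthesis, Dst (0.73; 0.41 on its other detected probe) and Pacsin3 (0.71; 0.40). Gm15107 was not detected with LIF and was at least 1.26-fold higher with PD0325901 and at least 1.31-fold higher with FGF2. Dgke and Pacsin3 were not detected with FGF2 and LIF, and with FGF2 were at least 2.17-fold and 1.24-fold higher. As for FGF2, the calls depended on the processing: with the value table of the authors, 0 genes passed in limma (734 at unadjusted p below 0.05), without a detection filter 8, and without background correction 346, of which 149 were higher.

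By gene list, 5 of 15 LIF-JAK-STAT3 targets fell over all genes tested (Socs3, Bcl3, Stat3, Klf4 and Junb) and 9 adjusted over the list alone, the others including Pim3 (−0.98), Cish (−0.72) and Bcl6 (−0.72), which was not detected with FGF2 and the inhibitor. The median of −0.72 lay below all 10000 random lists. Members not past either adjustment included Socs2 (−0.04) and the receptor genes Lifr (0.16) and Il6st (0.01). Naive pluripotency genes had a median of −0.32, also below all random lists. Of the 15, Klf4 fell, and 4 were lower adjusted over the list alone, the others being Tbx3 (−0.94), Gbx2 (−0.62) and Klf5 (−0.51). Further detected probes of Tbx3 gave −0.81 and −0.88. Nanog stood at −0.40, Klf2 at −0.38, Esrrb at −0.31, Zfp42 at 0.07 and Dppa5a at 0.04. General pluripotency genes had a median of 0.01 (percentile 57.3), with Tdgf1 called of 10 and also adjusted over the list alone, and with Pou5f1 at 0.03 and Sox2 at 0.05.

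Formative and primed epiblast genes had a median of 0.45 (0.19 without background correction), above all random lists, with 0 of 10 past the test. Adjusted over the list alone, 4 were higher and 1 lower: Pou3f1 (0.87), Otx2 (0.79), Zic2 (0.63), Car14 (0.51), which was not detected with LIF, and Cldn6 (−0.59). Amino acid and unfolded protein stress genes had a median of 0.46 (0.29 without background correction), also above all random lists, with 0 of 12 past the test and Chac1 and Psat1 higher adjusted over the list alone. Atf4 stood at 0.48 and Asns at 0.34, and 10 of the 12 members were higher in both backgrounds.

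BMP targets had a median of −0.27 (percentile 2.32), with Id1 called of 5 and Bmp4 (−0.62) also lower adjusted over the list alone. Their median was −0.51 (percentile 0.42) with PD0325901 but −0.0005 (45.9) with FGF2. Over both backgrounds it was −0.12 (3.17) without background correction. Primitive streak and mesendoderm genes had a median of −0.30 (percentile 2.48), which was −0.10 (2.96) without background correction. By background it was −0.24 (17.4) with PD0325901 and −0.34 (2.71) with FGF2. Of the 4 members, none was detected on every array and 0 passed the test. Gsc (−0.69) and Evx1 (−0.48) were lower adjusted over the list alone, neither being detected with the inhibitor. Of 10 primitive endoderm genes (median −0.07, percentile 16.7) Lama1 fell, and Gata6 (−0.60) was also lower adjusted over the list alone. Of 10 trophectoderm genes (median −0.15, percentile 3.37) none passed over all genes, and Tfap2c (−0.82) was lower adjusted over the list alone. Junb was the called gene of the 18 ERK feedback and immediate early genes (median −0.08, percentile 7.11) under either adjustment, and Tdgf1 that of the 5 Nodal and TGF-beta targets (0.13, 84.1). Glycolysis and hypoxia genes had a median of −0.10 (percentile 2.5), with 0 of 14 past either adjustment. No member passed either adjustment among genes of neuroectoderm (median 0.15, percentile 75.3), Wnt and beta-catenin targets (−0.03, 42.2), interferon response and MHC class I (−0.15, 3.1), cholesterol synthesis (0.03, 62.9), cell cycle (0.00, 46.3), p53 targets (−0.09, 7.41), heat shock (0.13, 94.2), the 2-cell-like state and germ cells (0.06, 68.3) and reference genes (−0.05, 21.2). By background, the cell cycle median was −0.22 (percentile 0.88) with PD0325901 but 0.08 (83.65) with FGF2. Fibroblast and feeder cell markers had a median of −0.52 (−0.27 without background correction), below all random lists, with 0 of 8 past the test and 4 lower adjusted over the list alone. That list stood at −0.59 with PD0325901 and at −0.19 with FGF2.

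**Figure D2:**
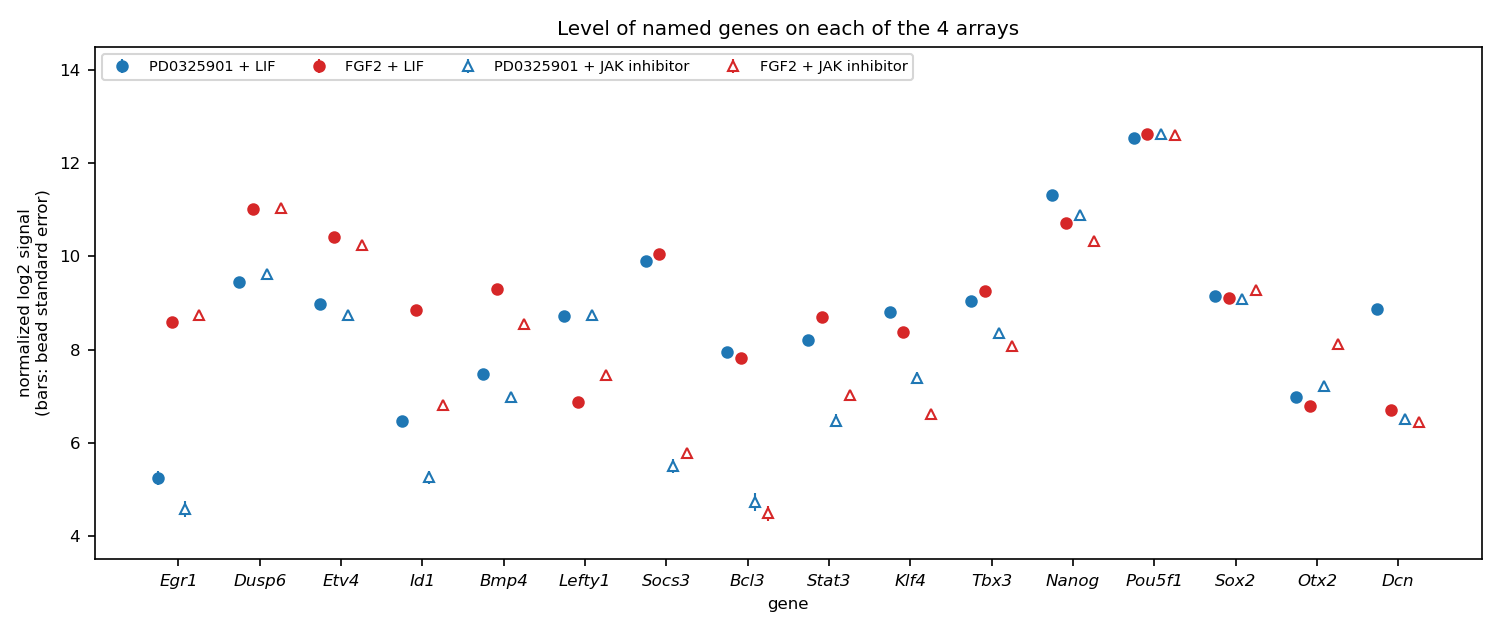
Normalized log2 signal (vertical axis) of 16 named genes on each of the 4 arrays; blue marks PD0325901, red FGF2, filled circles LIF and open triangles the JAK inhibitor, and bars are bead standard errors of that array, often smaller than the symbol. Egr1 separates the arrays by colour, Socs3 separates them by symbol (9.90 and 10.05 with LIF, 5.49 and 5.79 with the inhibitor), Pou5f1 lies between 12.55 and 12.62 on all 4, and Dcn stands at 8.86 with PD0325901 and LIF against 6.45 to 6.70 elsewhere.

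**Figure D3:**
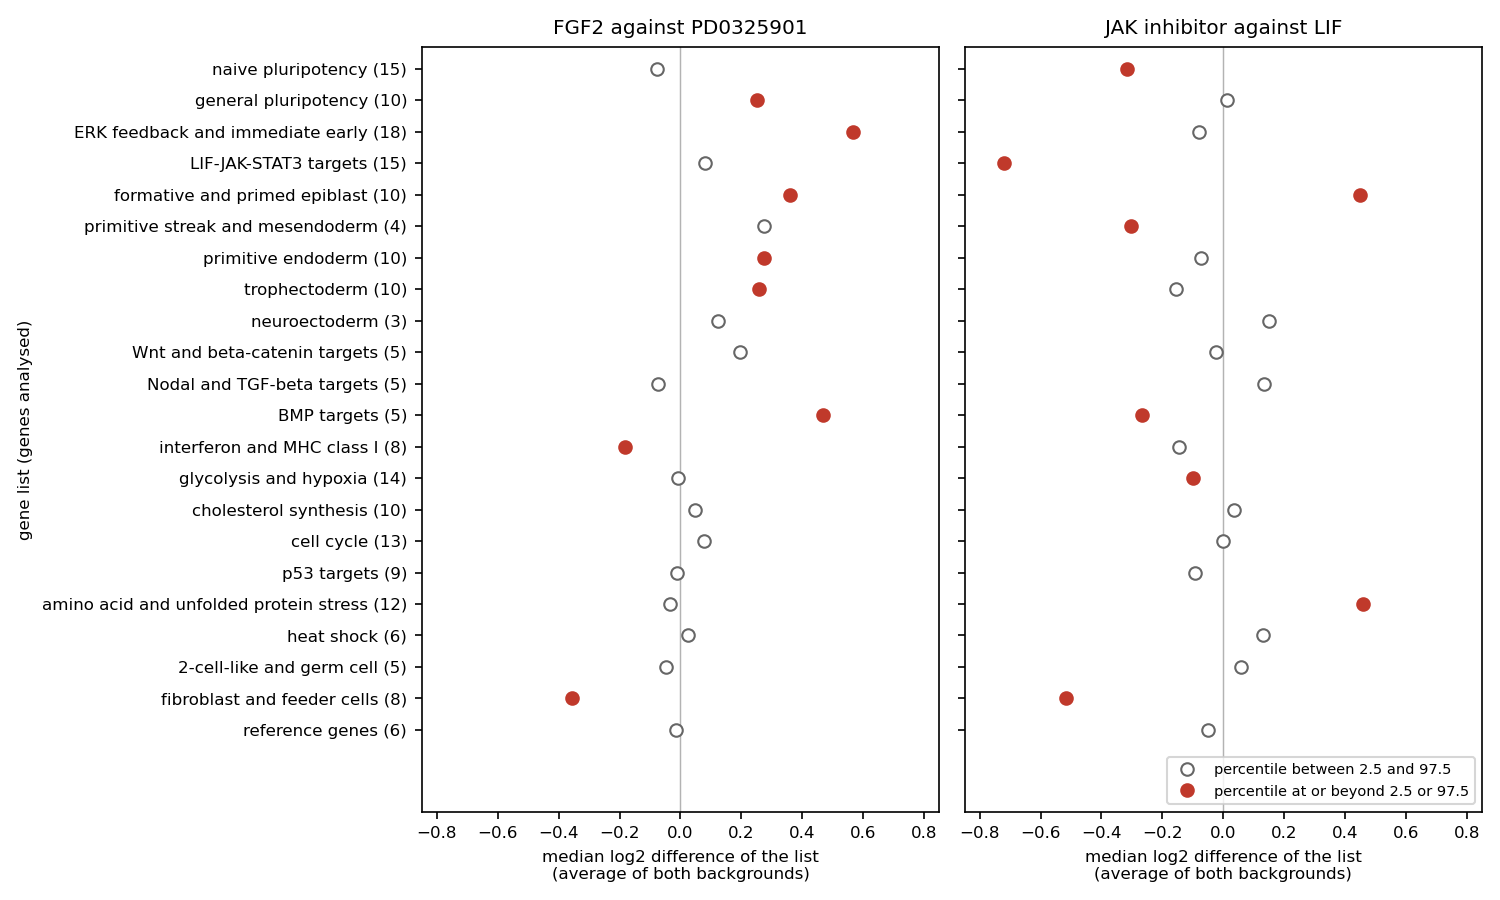
Median log2 difference (horizontal axis) of each of the 22 gene lists fixed before the data were examined, left for FGF2 against PD0325901 and right for the JAK inhibitor against LIF, with the number of analysed genes in brackets; filled points lie in the outer 5% of matched random lists. Percentiles were not adjusted for the number of lists. The ERK list stands at 0.57 at left, and the LIF-JAK-STAT3 list at −0.72 at right.

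The crossed design also gave the departure from additivity, the FGF2 difference with the JAK inhibitor minus the FGF2 difference with LIF, which has no test because no error is left once it is computed. It reached 2-fold in 127 genes, 67 above and 60 below 0, and with the value table of the authors more lay below 0 (288) than above (268). The largest positive values were those of Thbs2 (2.42), Dcn (2.11; 2.15 on its other detected probe), Saa3 (1.80), Rnf128 (1.80) and Sall2 (1.72), and the largest negative ones those of Rhbdf2 (−1.46), Inf2 (−1.45), Magea6 (−1.43), Aym1 (−1.29) and Zfp598 (−1.29). Most of these values rest in part on signals at the detection limit and their size and rank are uncertain: Thbs2 and Sall2 were not detected with FGF2 and LIF, Rnf128 with FGF2 and LIF or with PD0325901 and the inhibitor, Rhbdf2 with FGF2 and the inhibitor, Inf2 and Magea6 with PD0325901 and LIF, and Aym1 with PD0325901 and LIF or with FGF2 and the inhibitor. Among list members, Ccnd2 stood at 1.42, Lum at 1.26 and Spry4 at −1.02. Ccnd2 was not detected with PD0325901 and the inhibitor and Lum on either array with FGF2, and Psmb9, detected only with PD0325901 and the inhibitor, is given no value. Otx2, an epiblast transcription factor, had log2 signals of 6.98 with PD0325901 and LIF, 6.79 with FGF2 and LIF, 7.22 with PD0325901 and the inhibitor, and 8.13 with FGF2 and the inhibitor. The fibroblast list had a median departure of 0.60, above all random lists, Nodal and TGF-beta targets one of 0.44 (percentile 99.7), genes of the 2-cell-like state and germ cells one of 0.41 (98.7) and cell cycle genes one of 0.27 (99.6). Formative and primed epiblast genes, to which Otx2 belongs, had one of −0.30 (0.73). Without background correction 3 genes reached 2-fold, and 556 did so with the value table of the authors.

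Comparisons that used the array of PD0325901 with LIF held more 2-fold genes than those without it (103 and 69 against 33 and 45). Both comparisons without it used the array of FGF2 with the JAK inhibitor, so the counts cannot tell which of these arrays stood apart. The order depended on the processing. It was kept with median scaling (106 and 61 against 50 and 48), the value table of the authors (426 and 419 against 271 and 251), detection on all 4 arrays (69 and 42 against 23 and 35) and a size of 1.5-fold (791 and 786 against 390 and 390). It was lost in other settings, with 137 and 67 against 155 and 46 genes without normalization between arrays, 26 and 15 against 9 and 19 without background correction, 32 and 21 against 9 and 21 with normexp and an offset of 50, and 5 and 7 against 1 and 7 at 4-fold. The standard deviation of log2 differences over the brightest 25% of genes was 0.286 and 0.271 for the comparisons with that array, against 0.200 and 0.201 for the others. Of the genes named in advance, Cdx2, Fgf5, Sox1 and Sox17 had probes that were not detected on any array, and T and Tfcp2l1 had no probe under that symbol and were not analysed here.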

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

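All 7 tests of explanations in this part were chosen after the result was seen.

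A set of genes, many of them stromal, was highest on the array of PD0325901 with LIF, which flagged it as an array apart from the others: by normalized values, detected or not, 13 genes stood 2-fold or more above each other array there, against 4, 1 and 1 on the arrays of FGF2 with LIF, PD0325901 with the JAK inhibitor and FGF2 with the JAK inhibitor. They were the matrix genes Dcn, Thbs2, Col6a1, Lum and Prelp, the chemokine genes Ccl7 and Ccl8, Saa3, Rnase4, Ctsk, Igfbp7 and Rgcc, and Aqp3, which was called for both factors and had a departure from additivity of 0.03, so that its additive differences place it there. All 13 also had their highest deposited signal on that array (13 of 13), which their selection nearly fixed, but the gap of Dcn (492 against 140 to 173) and Saa3 (613 against 190 to 203) stood in the deposited signals before normalization, which was left open for the dimmer genes only; Ccl8 and Ctsk were detected on no other array, and against the detection limits of those arrays Ctsk did not reach 2-fold. Fibroblasts carried into that culture remain a candidate explanation: the 6 members of the fibroblast list outside the set were all higher there than the mean of the other arrays (median 0.37, percentile 99.87 of matched random lists), but Vim (10.13) was higher with FGF2 and LIF (10.37), Acta2 (11.49) with PD0325901 and the JAK inhibitor (11.51), and Col1a1 (6.70) was not higher than with FGF2 and the JAK inhibitor (6.69) by bead error, and probes of Col1a2, Col3a1 and Postn were not detected on any array. Per the labels the cultures were feeder-free, and an action of MEK inhibition joined with LIF on the genes other than Aqp3 cannot be told from a difference between cultures with 1 array per condition.

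More genes also differed 2-fold in the comparisons that used this array (103 and 69) than in the others (33 and 45). Both others used the array of FGF2 with the JAK inhibitor, so fewer such genes with that array would give the same order. The order was lost without normalization between arrays (137 and 67 against 155 and 46) and without background correction (26 and 15 against 9 and 19). It was kept with median scaling (106 and 61 against 50 and 48), the authors' value table (426 and 419 against 271 and 251) and detection on all 4 arrays (69 and 42 against 23 and 35), so whether the processing accounts for it was left open. As a percentage of signal, beads of the array of PD0325901 with LIF were not the noisiest. Their median standard error was 4.42%, against 4.56% with PD0325901 and the JAK inhibitor. On the log2 scale their median over the analysed genes was the highest by little, at 0.10821 against 0.10815 there. The array of FGF2 with the JAK inhibitor, used in both other comparisons, had the lowest values (4.08% and 0.0953), so bead noise was not excluded. Mean signal was highest with FGF2 and the JAK inhibitor (343). That of the array of PD0325901 with LIF, 294, lay between those of the other arrays (261 to 343). This does not exclude brightness given the counts without normalization. Among the brightest 25% of genes the standard deviation was 1.35 times as large in the comparisons with this array, which does not exclude dim probes as a source of the counts, and a difference between cultures and a joint action of the factors were not told apart.

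The calls for each factor were examined for an action of the other factor on them. The 24 genes called for the JAK inhibitor had a median FGF2 difference of −0.10 (percentile 4.1, 11 higher and 13 lower), and the 20 called for FGF2 had a median JAK inhibitor difference of 0.00 (percentile 41.46, 10 higher and 10 lower). Members went both ways, so the tests could not tell for either set. Of single genes, Id1 and Aqp3 were called for both factors in the additive fit, and for the others an action remains possible.

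Further genes were flagged because their difference had normalized values of opposite sign in the backgrounds, at least 1.5-fold on each side; the difference was not tested in any of them, and each rests on at least 1 array where the gene was not detected, so the size of the change is uncertain and for some the bounds lie under 1.5-fold. The FGF2 difference of Aym1 was 0.64 with LIF and −0.66 with the JAK inhibitor, a departure of −1.29; it was not detected with PD0325901 and LIF or with FGF2 and the JAK inhibitor, and the bounds were only 1.13-fold and 1.11-fold. That of Rhbdf2 was 0.62 and −0.84 (departure −1.46; not detected with FGF2 and the JAK inhibitor, bound 1.73-fold), and that of Rnf128 −0.72 and 1.09 (departure 1.80; not detected with FGF2 and LIF or with PD0325901 and the JAK inhibitor, bounds 1.55-fold and 1.48-fold). The JAK inhibitor difference of Ccnd2 was −0.71 with PD0325901 and 0.71 with FGF2 (departure 1.42; not detected with PD0325901 and the JAK inhibitor, bound 1.44-fold). That of Rnf128 was −1.14 and 0.67 (departure 1.80; bounds 1.53-fold and 1.501-fold), and that of Thbs2 −1.74 and 0.68 (departure 2.42; not detected with FGF2 and LIF, bound 1.59-fold).

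Of 711 detected probes without a gene symbol, which the comparisons did not use, 3 differed at least 2-fold the same way in both backgrounds, and the difference was not tested. Probe ILMN_3161263 stood at a mean of −1.003 and ILMN_2879102 at −1.12 for the JAK inhibitor against LIF, and ILMN_2757617, not detected with PD0325901 and the JAK inhibitor, at 1.55 for FGF2 against PD0325901.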

How the results depend on the processing

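No test of this part was chosen after the result was seen; the alternatives were fixed in advance. No paired analysis was possible because each condition had 1 array. Signal over background limits what can be seen: a probe under 10 above background returned a median of 0.10 of a simulated log2 change of 1. The called genes that could be tested kept their direction in each refit, with the authors' value table covering 19 and 22 of them and detection on all 4 arrays 16 and 21; the additive fit cannot be run with an array left out. The larger side of some counts turned: the share of higher genes went from 20% to 52.2% for the JAK inhibitor with FGF2 without normalization, from 21.7% to 51.8% for it with PD0325901 at 1.5-fold, from 55.3% to 40% for FGF2 with LIF at 4-fold (2 of 5 genes), and for the departure from 52.8% to 49.1% with median scaling, 48.2% with the authors' value table, 45.3% with detection on all 4 arrays and 44.9% at 1.5-fold. All 20 FGF2 calls and 24 JAK inhibitor calls stayed past the test except with the authors' value table (0 of 19 and 0 of 22 tested), without a detection filter (0 of 20 and 8 of 24) and at adjusted p 0.01 (5 and 9). Of the called genes detected on all 4 arrays, 16 of 16 and 21 of 21 stayed. The mean of a gene's probes, the robust prior (20 and 24) and an adjusted p of 0.1 (29 and 36) moved no count by more than 1.5 times. The counts hung on the processing as follows, in the order FGF2 with LIF, FGF2 with the JAK inhibitor, JAK inhibitor with PD0325901 and JAK inhibitor with FGF2 (here 103, 33, 69 and 45); both backgrounds for FGF2 and the JAK inhibitor (20 and 23); additive fit (20 and 24); departure (127); factor means (39 and 34). The cause was not tested except where named.

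Without background correction they were 26, 9, 15 and 19; 9 and 11; 400 and 346; 3; 11 and 14. The additive calls were then 59% and 43.1% higher (from 85% and 0%). With normexp and an offset of 50 they were 32, 9, 21 and 21; 9 and 13; 335 and 280; 4; 14 and 18. The additive calls were then 58.5% and 40.7% higher. Both keep a larger constant in the signal, which by construction shrinks differences. With scaling to the median of detected probes, FGF2 with the JAK inhibitor held 50 genes and the additive fit 234 and 154.

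Without normalization between arrays, FGF2 with the JAK inhibitor held 155 genes, both backgrounds for FGF2 35, the additive fit 444 and 49, and the FGF2 mean 67. The median of all genes then shifted to 0.14 for FGF2 with LIF, 0.42 for FGF2 with the JAK inhibitor, −0.08 for the JAK inhibitor with PD0325901, 0.20 for it with FGF2, and 0.28 for the FGF2 mean. The share of higher genes went from 55.3% to 81.0% for FGF2 with LIF and 69.7% to 99.4% for FGF2 with the JAK inhibitor. It went from 85% to 97.1% for FGF2 in both backgrounds, 52.8% to 87.5% for the departure and 61.5% to 94.0% for the FGF2 mean. In the additive fit it went from 85% to 95.5% for FGF2 and from 0% to 18.4% for the JAK inhibitor. With median scaling it was 58.0% for FGF2 with the JAK inhibitor, and 57.7% and 26.6% in the additive fit.

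With the authors' value table the counts were 426, 271, 419 and 251; 67 and 62; 0 and 0 in limma, with 768 and 734 at unadjusted p below 0.05; 556; 158 and 140. The share of higher genes was then 58.3% for FGF2 with the JAK inhibitor, 47.3% and 42.2% for the JAK inhibitor with PD0325901 and with FGF2 (from 21.7% and 20%), 64.2% and 30.6% in both backgrounds (from 85% and 0%), and 37.9% for the JAK inhibitor mean (from 5.88%). Without a detection filter the additive limma fit gave 0 and 8, with 1588 and 1469 at unadjusted p below 0.05. With detection on all 4 arrays the JAK inhibitor with PD0325901 held 42 genes, the additive fit 60 and 47, and the departure 53, over fewer genes tested. With detection p below 0.05 the additive fit gave 66 and 45, and with an intensity trend 360 and 296, of which 60% and 39.9% were higher. The share was 65% and 12.8% with detection on all 4 arrays and 65.2% and 11.1% with detection p below 0.05.

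By construction, size thresholds moved the counts: at 1.5-fold they were 791, 390, 786 and 390; 106 and 90; 1017; 251 and 209, and at 4-fold 5, 1, 7 and 7; 1 and 5; 2; 1 and 5. Leaving out an array left 1 background per factor, so it repeated counts above (33 or 103 genes for FGF2, 45 or 69 for the JAK inhibitor).

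The gene lists were refitted with the authors' value table, without background correction and with detection on all 4 arrays, and 35 of 130 medians moved by more than their spread between the backgrounds. The ERK list's FGF2 median of 0.57 became 1.00, 0.24 and 0.83, above all matched random lists each time, and the LIF-JAK-STAT3 list's JAK inhibitor median of −0.72 became −0.38 without background correction, below all of them. Medians in the outer 5% that shrank by more than 1.5 times without background correction included those of primitive endoderm (0.27 to 0.17) and trophectoderm genes (0.26 to 0.10) for FGF2. They also included primitive streak genes (−0.30 to −0.10) and BMP targets (−0.27 to −0.12) for the JAK inhibitor. With detection on all 4 arrays BMP targets became 1.08 and −0.44, primitive endoderm genes 0.18 and fibroblast markers −0.20 and −0.28. With the authors' value table primitive streak genes became −1.35, but too few members were left there for a percentile. With detection on all 4 arrays no member of that list was left. For FGF2, trophectoderm genes left the outer 5% with the authors' value table (percentile 97.03). With detection on all 4 arrays primitive endoderm genes (95.2) and fibroblast markers (2.77) left it, and LIF-JAK-STAT3 targets entered it (98.3). For the JAK inhibitor, primitive streak genes (2.96), BMP targets (3.17) and glycolysis genes (2.97) left it without background correction, glycolysis genes also with detection on all 4 arrays (4.22). Interferon and MHC class I genes entered it under all 3 alternatives (0.24, 0.24 and 0.36).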

Other observations

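No test of this part was run beyond those above.

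Further genes passed the additive limma fit that the report does not name. Higher with FGF2 were Exoc3l (1.45), Pdyn (1.42), which encodes an opioid peptide precursor and was not detected with PD0325901 in either background, the zinc finger gene Zfp423 (1.37) and Vgf (1.19), a gene induced by nerve growth factor in neurons, as mean log2 differences over both backgrounds. Lower with the JAK inhibitor were Hal (−1.58), whose product breaks down histidine, the adhesion molecule gene Icam1 (−1.46), the riboflavin transporter gene Slc52a3 (−1.20), Upp1 (−1.16), whose product breaks down uridine, and Irak3 (−1.10), a regulator of Toll-like receptor signalling; they were not tested as groups. The kinase gene Sgk1 stood at −1.12, the small GTPase gene Mras at −1.29, the small heat shock gene Hspb8 at −1.05, the hormone precursor gene Trh at −1.15, Prr13 at −1.17 and Spats1 at −1.11. The 2 factor means correlated across genes with r = 0.05, and genes are not independent replicates.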
